A study of Mus musculus with 4 samples.

How the data were processed

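Biotin-labelled material from total RNA of epididymal fat was measured on 4 Affymetrix mouse genome arrays, and the labels speak of 2 mice per diet. The deposited values are intensities, 1 linear signal for each of 45101 probe sets on 4 arrays. RMA is named in the submitters' processing notes, with no version given. The deposited intensity values do not have the form of log2 RMA output: they are linear, the lowest value on each array is its median divided by 100, and a value of 1 lies above 88.5% to 88.6% of the probe sets of each array. How the authors scaled the intensities is not given in the sources used here, so the scale of each array is open. Between 11 and 75 probe sets per array sit at the lowest value, and values there have no order.

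The intensities were log2 transformed without an added constant or a further normalization. Probe sets were named through the platform annotation, in which 34958 had 1 gene symbol, 932 had several and 9211 had none; 34754 matched a current gene record through the Entrez identifier and 0 symbols changed. The assembly named with those gene records served for names only, and no coordinates are given because the series names no genome build. Each gene was represented by the probe set with the highest mean log2 value over the 3 arrays with a labelled diet, which gave 18193 genes. Adrb3, fixed for report in advance, is not analysed here.

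The groups were 2 high-calcium whey arrays and 1 standard high-fat array, as the labels give them, and the array with an open diet entered no fit. Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 1 residual degree of freedom and 2.38 in all after moderation, and intervals at 95% used these. Tests of 40 gene lists written before the data were examined used camera with a preset inter-gene correlation of 0.01. Estimated correlation, ranks and fry were alternatives. Camera with the estimated correlation rests on the 1 residual degree of freedom, which the preset form does not. A call lost there is therefore weak evidence against a list whose estimated correlation is not above the preset one. Where the estimate is far above it, the preset form can overstate the evidence for a list. Each list's median was also set against 10000 random lists matched on mean signal in 100 bins, drawn with replacement. fry asks whether a list's genes move one way on balance and does not compare them with other genes.

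The rule for named genes was also set before the data were examined. It took up to 15 genes in each direction by size among those past the threshold with both high-calcium arrays on the same side, filled up from genes with an unadjusted p under 0.01, and left out RIKEN, Gm and LOC symbols. It added 3 members of each described list by size and a fixed set of adipocyte genes. Because the rule led to dim genes, background was afterwards set at the median of each array. The 95th percentile of 44 olfactory receptor probe sets lay between 0.850 and 1.14 times that median. A gene under it on every array of 1 group and above it on every array of the other was given only a bound, and the list members named were limited, at the same stage, to those above it on all 3 arrays. A second ranking of genes above background on all 3 arrays and at least 1.5-fold apart on both high-calcium arrays, by the smaller of the 2 differences, was added then too, as was a simulation of unchanged arrays that share the standard array.

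The procedure was tested on simulated data for this comparison, with 200 of 18193 genes changed. With the spread seen between the high-calcium arrays it called 0% of genes changed by 1, 2 or 4 log2 units, while the mean estimates were 0.97, 1.83 and 4.08. With a tight spread (SD 0.1) it called 100% at each size, with 14 false calls. A simulated list of 25 genes shifted by -0.4 gave a camera p of 0.0149 with the observed spread. Log2 signal ratios of 3' over 5' control probe sets, a check of RNA integrity, were -0.44, -0.44, -0.42 and -0.54 for Gapdh and 0.76, 0.65, 0.69 and 0.52 for beta-actin, in the order high-calcium replicates 1 and 2, standard array and array of open diet.

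Alternatives were the mean of all probe sets of a gene, leaving out probe sets that can share transcripts, a filter on dim genes, quantile normalization, centring on array medians, limma with a trend and robust estimation, every probe set by itself, other thresholds, and leaving out each high-calcium array. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.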

Results

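Gene expression was measured in epididymal fat, the visceral fat pad beside the testis, of C57BL/6J mice that had been fed a high-fat diet supplying 60% of energy as fat from 9 weeks of age for 21 weeks. One diet held 1.8% calcium with whey protein isolate and the other, the standard high-fat diet, held 0.4% calcium. The feeding study had 10 mice per diet, and epididymal fat of 2 mice per diet was profiled on Affymetrix mouse genome arrays, which carry 45101 probe sets. Labels placed 2 arrays on the high-calcium whey diet and 1 array on the standard diet. The diet of the remaining array stayed open. Its title repeats the wording of the series title, and that wording also stands in a label of high-calcium replicate 2, whereas the stated 2 mice per diet would leave it as a control. It entered no comparison. If the shared wording names a diet, the high-calcium arrays would outnumber the stated 2 mice, and a label among them, that of replicate 1 included, would be in doubt.

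The question addressed was how calcium and whey protein in a high-fat diet alter the expression profile of adipose tissue. The 3 arrays with a labelled diet gave values for 18193 genes. Median signal on the deposited linear scale was 0.0963 on high-calcium replicate 1, 0.0628 on high-calcium replicate 2 and 0.0624 on the standard array. A gene was taken as above background where its signal exceeded the median of that array, and 10620 genes did so on all 3 arrays. The number of arrays limits the precision throughout, because the spread came from 2 high-calcium arrays and the single standard array was assumed to vary alike. A difference between the diets could therefore not be separated from a difference between that 1 standard-diet mouse and the others.

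Endothelial genes were lower on both high-calcium arrays. Of 25 measured genes of the endothelium list, 20 were lower on both arrays and 3 were higher on both, with a median log2 difference of -0.32. The median was -0.31 on replicate 1 and -0.39 on replicate 2. Sox18, a transcription factor of vascular endothelium, differed by -0.94 (SE 0.35) and Aplnr, the apelin receptor, by -0.82 (SE 0.36). Tie1, an endothelial receptor tyrosine kinase, differed by -0.76 (SE 0.32). On the array of open diet Sox18, Aplnr and Tie1 had log2 signals of -0.79, 1.11 and -3.27. On the standard array they had -0.088, 2.04 and -2.48. Among measured members only Kdr, Pdpn and Rgcc were not lower on the array of open diet than on the standard array. The standard array thus stood apart from the array of open diet as well. The list passed limma's camera test with a preset correlation (adjusted p = 1.17e-04), and its median lay below that of all 10000 random lists matched on mean signal. The macrophage list, which was lower on replicate 1 only, and the thermogenic list, which did not pass camera over all genes, reached that too. Random lists hold unrelated genes, so this place is weak evidence for a list of genes that vary together. The call was lost with an estimated correlation (adjusted p = 0.996) and with fry (adjusted p = 0.995). It was also lost where each array was centred on its own median (adjusted p = 0.211), although the list median was then -0.65 and that of all genes -0.24, against -0.32 and 0.080 as deposited. Over all alternatives the adjusted p ranged from 7.21e-09 to 0.996.

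Genes of branched-chain amino acid breakdown, the mitochondrial route that degrades leucine, isoleucine and valine, were lower on both high-calcium arrays. Of 25 measured members 20 were lower on both arrays and 2 were higher on both, with a median log2 difference of -0.18. The largest differences were those of Dbt (-0.51, SE 0.38), a subunit of the branched-chain keto acid dehydrogenase, Bcat1 (-0.49, SE 0.60), a transaminase, and Mccc1 (-0.45, SE 0.33), a subunit of methylcrotonyl-CoA carboxylase. Replicate 1 carried the value of Bcat1, at -0.94 against -0.040 on replicate 2, whereas Dbt was at -0.32 and -0.70. The list passed camera with the preset correlation (adjusted p = 0.0133). The call was lost in the setting with an estimated correlation and with fry. The correlation estimated for this list, -0.027, was under the preset 0.01, so correlation among its genes did not end the call. Quantile normalization (adjusted p = 0.173) and centring on the array medians (adjusted p = 0.380) ended it too. The list median was -0.18 after quantile normalization too and -0.50 after centring. Over all alternatives the adjusted p ranged from 7.85e-04 to 0.996.

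Macrophage genes were lower on high-calcium replicate 1 and not on replicate 2. The list of 36 measured genes had a median log2 difference of -0.42 and passed camera with the preset correlation (adjusted p = 0.010), but not with the estimated one (adjusted p = 0.996), nor without probe sets that can share transcripts (adjusted p = 0.0585), after quantile normalization (adjusted p = 0.146) or on median-centred arrays (adjusted p = 0.134). The list median under these last 3 settings was -0.41, -0.41 and -0.74. The correlation estimated for this list was 0.51, far above the preset 0.01, so the preset form can overstate the evidence for it. Over all alternatives the adjusted p ranged from 4.31e-04 to 0.996, and 12 members were lower on both arrays and 3 higher. Replicate 1 decided the value: the median was -0.90 there and 0.092 on replicate 2, so that without replicate 1 the direction turned. Trem2, a lipid receptor of macrophages, differed from the standard array by -1.84 on replicate 1 and by -0.09 on replicate 2. Fcgr1, an Fc receptor, differed by -1.35 and -0.53 on the same arrays. Retnla, a product of alternatively activated macrophages, lay on the other side, at 1.11 and 0.56. Cd68, a general macrophage marker, had a log2 signal of 1.89 on replicate 1, 3.16 on replicate 2 and 2.93 on the standard array.

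The 2 high-calcium arrays also differed from each other in genes of other cell types. The smooth muscle list had a median log2 difference from the standard array of 1.71 on replicate 1 and of -0.50 on replicate 2. Over its 16 members above background these medians were 0.80 and -0.37, and that of replicate 1 was 0.63 after quantile normalization. Myh11, the smooth muscle myosin heavy chain, had a log2 signal of 2.12 on replicate 1, -2.98 on replicate 2 and -2.08 on the standard array. Tpm2, a muscle tropomyosin, had values of 4.11, -0.44 and 0.49 on these arrays, and Des, the muscle intermediate filament desmin, had 0.38, -1.77 and -2.08. B-cell genes had medians of 1.07 and -0.08 on the 2 high-calcium arrays, with Fcmr at 2.68 and -0.47 and Cd79b at 2.26 and -0.45. Over the 15 B-cell genes above background the medians were 0.38 and 0.020. Skeletal muscle genes, 7 of 31 above background on all 3 arrays, had medians of 1.51 and -0.072, and over those 7 genes the medians were 0.21 and -0.072. Of 23 measured genes of the testis, epididymis and vas deferens, only 3 were above background on all 3 arrays, namely Lcn2, Prm1 and Prm2. The sperm protamine Prm1 had log2 signals of -0.20 on replicate 1, -0.30 on the standard array and -2.60 on replicate 2. On these arrays in turn Prm2 had -0.29, -0.72 and -3.61. On the array of open diet Prm1 and Prm2 were low as well, at -3.69 and -5.76. Defb42, under background on replicate 2, had 3.25 on replicate 1, -3.21 on the standard array and -4.48 on replicate 2. Over all 23 measured genes, most of them dim, the medians were 0.78 on replicate 1 and -1.92 on replicate 2. None of these lists passed camera, with adjusted p of 0.982 for smooth muscle, 0.859 for B cells, 0.232 for skeletal muscle and 0.197 for the reproductive tract. For smooth muscle the median over both arrays was positive at 0.65, whereas camera's direction was down. Over members above background on all 3 arrays, the median gap between the 2 high-calcium arrays exceeded the median difference between the diets in 27 of the 40 lists. Some of these lists had as few as 2 such members.

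**Figure D1:**
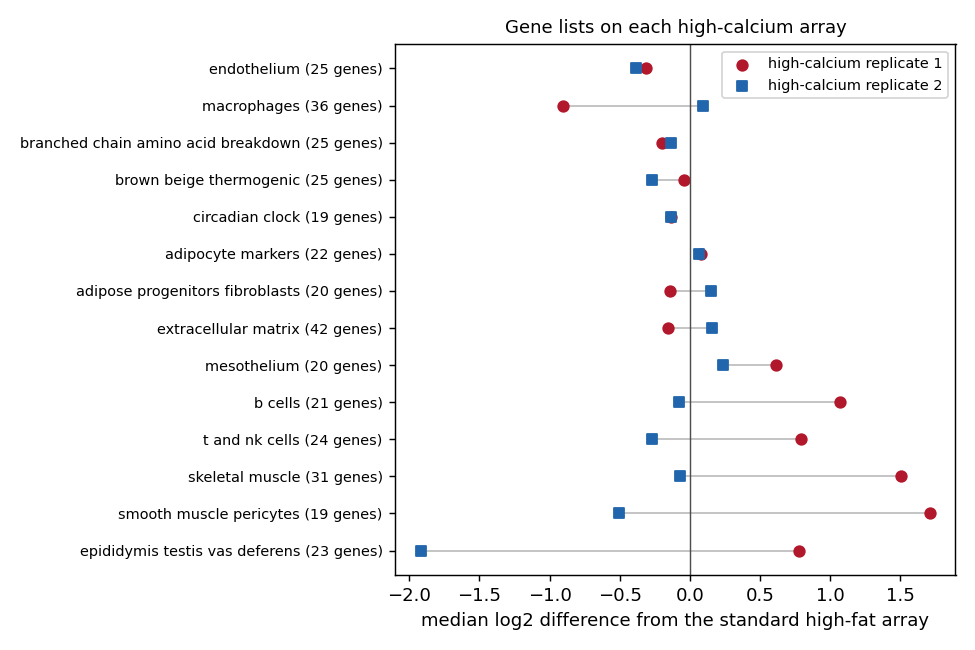
Median log2 difference from the standard high-fat array over the measured genes of 14 lists, dim genes included (vertical axis, with the number of genes), for high-calcium replicate 1 (circles) and replicate 2 (squares). The endothelium medians lie close together at -0.31 and -0.39, whereas the smooth muscle medians lie at 1.71 and -0.50, or at 0.80 and -0.37 over genes above background.

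Mesothelial genes, which mark the lining of the fat pad, were higher on both arrays for 12 of 20 measured members and lower on both for 1. Upk3b differed by 1.08 (SE 0.41), Upk1b by 1.05 (SE 0.44) and Msln, mesothelin, by 0.94 (SE 0.55), with 1.34 on replicate 1 and 0.54 on replicate 2. The list did not pass camera over all genes (adjusted p = 0.197) and passed with the filter planned in advance, genes above the median signal (adjusted p = 0.0167). It also passed over genes above background, a restriction chosen after the data had been seen, with the preset correlation (adjusted p = 0.00201) but not with the estimated one (adjusted p = 0.960). Thermogenic genes of brown and beige fat did not pass over all genes either (adjusted p = 0.0693), passed with the planned filter (adjusted p = 0.00383) and, over genes above background, passed with the preset correlation (adjusted p = 0.0143) but not with the estimated one (adjusted p = 0.960). Of their 15 genes above background 9 were lower on both arrays and 4 higher, with medians of -0.084 on replicate 1 and -0.27 on replicate 2. Among them Cidea, a lipid droplet protein, differed by -1.23 (SE 0.35), Prdm16, a determinant of brown fat identity, by -1.05 (SE 0.36) and Esrrg by -1.01 (SE 0.39). Esrrg turned to 0.31 with the mean of all its probe sets. The circadian clock list had an adjusted p of 0.190 over all genes, of 0.0305 with the planned filter and, over those above background, of 0.00575 with the preset correlation and 0.960 with the estimated one. Members above background included Usp2 at -1.01 (SE 0.33), Dbp at -0.61 (SE 0.37) and Per3 at -0.52 (SE 0.48), with -0.21 on replicate 1 and -0.84 on replicate 2. Per3 turned to 0.35 with the mean of its probe sets, and Dbp to 0.029 without probe sets that can share transcripts. Of the 40 lists, 10 had an unadjusted camera p under 0.05 with the preset correlation and 3 passed. With the estimated correlation 0 passed and 0 had an unadjusted p under 0.05, the smallest being 0.121, and fry likewise gave 0 and 0. limma with its constant prior, on the values as deposited, called 0 members of any list when adjusted over the list alone, as over all genes.

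No single gene passed the threshold between the diets with limma's constant prior on the values as deposited. This test called 0 of 18193 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.977. At an unadjusted p under 0.05 there were 729 higher and 162 lower genes, where 909.65 genes in all would be expected by chance. Of the 10620 genes above background, 19 had an unadjusted p under 0.05 and 0 had one under 0.01, where 531 and 106.2 would be expected by chance. The constant prior, set over all genes, was thus conservative for genes above background. It also sets most of the SE of a steady gene: Irs3 had an SE of 0.32 with an SD of 0.001 between the high-calcium arrays. With a mean-variance trend and robust estimation limma called 6 genes, all lower: Lcn2, Gja1, Calml4, Mmp7, Fbp1 and S100a8, with adjusted p from 5.83e-04 to 0.0460. S100a8, a neutrophil calcium-binding protein that differed by -1.12, is outside the rule for named genes and was picked after its value was seen. Centring the arrays on their medians gave 66 higher and 37 lower genes, of which 0 were above background on all 3 arrays.

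The genes with the largest differences at an unadjusted p under 0.01, none of which passed the adjusted threshold with the constant prior on values as deposited, were mostly dim. Of these 30 genes 22 passed on median-centred arrays and 1, Mmp7, with a trend and robust estimation. Of 15 genes higher by this rule 12 were not above background on any array. Fgf4 was above background on both high-calcium arrays and at least 2.63-fold higher than on the standard array, and D6Ertd474e and Vmn1r54 were above background on 1 high-calcium array each. Of 15 lower genes 11 were above background on the standard array. Mmp7, a matrix metalloproteinase of glandular epithelium, was at least 22.9-fold lower on the high-calcium arrays, Tmem212 at least 11.9-fold, Slc7a9, a cystine transporter subunit, at least 8.65-fold, and Iyd, iodotyrosine deiodinase, at least 7.55-fold. Each bound sets the mean log2 signal of the brighter group against the background level of the dimmer one, with an adjusted p of 0.977 from limma in each case.

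Genes measured above background on all 3 arrays were ranked separately, a choice made after values had been seen. By this ranking the lower genes were led by Fbp1, fructose-1,6-bisphosphatase, at -3.04 and -3.56 on the 2 arrays and a mean of -3.30 (SE 0.44). Lcn2, the iron-siderophore carrier lipocalin 2, had a log2 signal of -1.36 ± 0.43 (SD, n = 2) on the high-calcium arrays and of 1.80 on the standard array, an 8.95-fold difference. Adgrg2, an adhesion receptor of the efferent ducts, was 7.15-fold lower, with 4.68-fold on replicate 1 and 10.9-fold on replicate 2. Calml4 was 4.84-fold lower, Cfi, complement factor I, 5.25-fold lower and the chemokine Ccl28 4.65-fold lower. Gja1, the gap junction protein connexin 43, was 2.89-fold lower and the glutathione transferase Gstm7 2.73-fold lower. On the array of open diet Fbp1, Calml4 and Adgrg2 had log2 signals of -3.66, -1.78 and -2.26. On the standard array they had -0.15, 0.77 and 0.61. The other lower genes named in this ranking were lower on the array of open diet than on the standard array too. Higher genes included Gpank1 (3.79-fold), Lama5, a laminin chain of basement membranes (2.80-fold), Cit, citron kinase (2.70-fold), Arid5a (2.94-fold) and Ccl24, an eosinophil chemokine (2.62-fold). None of these passed limma's adjusted threshold with the constant prior on values as deposited, whereas Fbp1, Lcn2, Calml4 and Gja1 passed with a trend and robust estimation.

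By size alone, 2316 genes were at least 1.5-fold higher and 805 at least 1.5-fold lower on both high-calcium arrays, while the 2 high-calcium arrays differed from each other by as much on 7716 genes. Over genes above background the counts were 238 and 116, against 2057 between the high-calcium arrays. Both differences share the standard array, and 100 simulations of unchanged arrays with the spread seen between the high-calcium arrays gave means of 428.8 higher and 427.8 lower genes, a comparison added after the data had been seen. The observed counts were below these. The spread used was wide, with an SD of 0.52 between the high-calcium arrays against 0.36 between replicate 2 and the standard array. The simulated arrays were thus noisier than that pair, and the comparison cannot decide whether the diets differ. With replicate 2 alone 407 genes above background were higher and 548 lower, and with replicate 1 alone 1479 were higher and 584 lower.

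Genes of adipocyte function fixed for report in advance did not pass limma's test. Lep, the satiety hormone leptin, had a log2 signal of 3.60 ± 0.03 (SD, n = 2) against 3.16, a difference of 0.44 with a 95% interval from -0.74 to 1.62. Adipoq, adiponectin, differed by -0.03 (SE 0.33), with 0.028 on replicate 1 and -0.096 on replicate 2, and Pparg, the regulator of fat cell formation, by -0.19 (SE 0.33), with -0.27 and -0.098. The lipid synthesis genes Fasn and Scd1 differed by 0.28 (SE 0.33) and 0.17 (SE 0.34), and both turned negative where arrays were centred on their medians, at -0.048 and -0.16, a setting in which the median of all genes lay at -0.24. Scd1 was at 0.28 on replicate 1 and 0.057 on replicate 2. Hsd11b1, which regenerates active glucocorticoid, differed by -0.40 (SE 0.54) and Agt, angiotensinogen, by -0.36 (SE 0.58). Replicate 2 carried both values, since Hsd11b1 was at -0.0065 on replicate 1 and -0.79 on replicate 2, and Agt at 0.072 and -0.78. For insulin action, Insr differed by 0.18 (SE 0.36), turning to -0.15 on median-centred arrays, Irs1 by -0.16 (SE 0.35) and the glucose transporter gene Slc2a4 by 0.35 (SE 0.37). On replicates 1 and 2 in turn Insr was at 0.32 and 0.034, Irs1 at -0.022 and -0.30, and Slc2a4 at 0.52 and 0.18. Grb14, an adaptor that binds the insulin receptor, differed by -1.21 (SE 0.35), Irs3 by 0.68 (SE 0.32) and Rapgef1 by 0.61 (SE 0.39), with 0.81 on replicate 1 and 0.40 on replicate 2, which turned to -0.092 with the mean of its probe sets. The insulin signaling list had a median of -0.03 (camera adjusted p = 0.197). Among secreted factors Ccl2, a monocyte chemokine, differed by 0.94 (SE 0.35) and Sfrp5, a Wnt antagonist, by 1.15 (SE 0.34), while the chemokines Ccl8 and Cxcl13 differed by -1.23 (SE 0.73) and -1.14 (SE 1.20). Replicate 2 carried the latter values, with Ccl8 at -0.64 on replicate 1 and -1.82 on replicate 2, and Cxcl13 at -0.11 and -2.17. The adipokine and inflammatory cytokine lists had adjusted p of 0.197 and 0.158. Ucp1, the uncoupling protein of brown fat, and Vdr, the vitamin D receptor, were not above background on any of the 3 arrays.

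**Figure D2:**
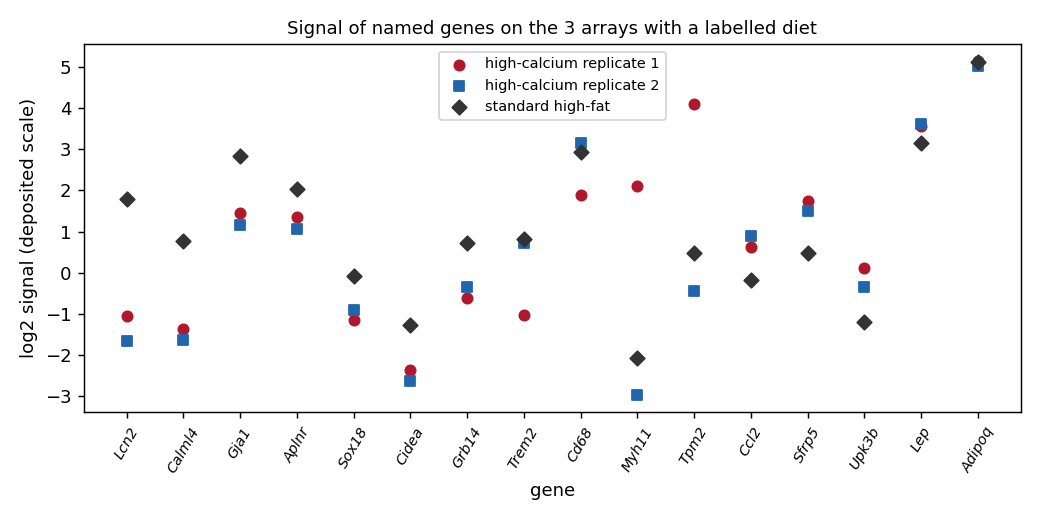
Log2 signal on the deposited scale (vertical axis) of 16 named genes on high-calcium replicate 1 (circles), high-calcium replicate 2 (squares) and the standard high-fat array (diamonds). Lcn2 lies at 1.80 on the standard array and at -1.05 and -1.66 on the high-calcium arrays, whereas Myh11 lies at 2.12 on replicate 1, -2.98 on replicate 2 and -2.08 on the standard array.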

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

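On the array of open diet, 174 genes were above background that were above background on none of the other 3 arrays, which is signal in a sample outside the comparison. The same count for the other arrays was 631 for high-calcium replicate 1, 283 for high-calcium replicate 2 and 320 for the standard array.

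Of the tests below, those on the second smooth muscle list and on the epithelium list were set before their values were seen, and the others were chosen only after the result was seen. The latter are those after quantile normalization, on replicate 2, on genes of like signal and on 4 cell lists set against the endothelium list. Intervals in these tests resample genes on the same arrays. Genes are not independent replicates, so the intervals hold no spread between mice and can be too narrow. Smooth muscle genes were higher on high-calcium replicate 1 than on the standard array, with Tpm2 at a log2 signal of 4.11 against 0.49 and Myh11 at 2.12 against -2.08. A second smooth muscle list of 20 genes was written after the arrays had been seen. Of its genes 14 were above background on all 3 arrays and 0 were in another fixed list. The median log2 difference of these 14 on replicate 1 was 1.35 (95% bootstrap interval 0.42 to 1.80). The list would be higher under any cause of more smooth muscle RNA in that sample. It therefore cannot decide between causes, and tissue with smooth muscle carried along with the fat pad is only a candidate explanation. A diet effect shared by both mice is argued against, since the members of the fixed list above background had a median of -0.37 (interval -0.66 to -0.10) on replicate 2. Scaling or background of the array is argued against as well: after quantile normalization their median on replicate 1 was 0.63, against 0.80 as deposited, and 0 of 10000 random lists matched on signal, or 0%, reached it, the highest being 0.37. A wrong label was not tested and stays open.

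Lcn2, Adgrg2 and Mmp7, which are also expressed by epithelia of the male tract, were lower on both high-calcium arrays than on the standard array. They were lower on the array of open diet too. A candidate explanation was epithelium carried along on the standard array, but the epithelium list, with 0 genes in another fixed list and 19 above background on the standard array, was higher on replicate 1 by a median of 1.45 (interval 0.33 to 1.79). On replicate 2 its median was -2.39, a value that rests in part on signals under background there. Cdh1, for instance, had a log2 signal of 0.12 on replicate 1, -5.51 on replicate 2 and -1.33 on the standard array. Epithelial signal thus varied between the high-calcium arrays themselves, though its size on replicate 2 is not exact. The choice of genes above background on the standard array also favours lower values elsewhere. A list lower on both arrays, set in advance for that explanation, was not seen. Of the 19 genes 4 were lower on replicate 1 and 16 on replicate 2. Epithelium on replicate 1 would hide more epithelium on the standard array, so the test cannot decide that question. A particular epithelium, the diet and a trait of the single standard-diet mouse stay open and untested as well. Scaling by signal level was examined in the 50 other genes nearest in mean signal to each of 26 named lower genes. The 26 had a median of -2.77, values under background included, and their neighbours had medians from -0.064 (interval -0.15 to 0.017) to 0.46. Where the named gene was under background on a high-calcium array, its neighbours were not of like signal on each array. For such genes the comparison cannot decide. Around those above background on all 3 arrays the medians ran from -0.064 to 0.22, which argues against scaling for them.

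Endothelial genes were lower on both high-calcium arrays, and most were lower on the array of open diet too. On the 2 high-calcium arrays a lower share of all cells other than adipocytes, as the whole cause, is argued against by the mesothelial genes only. They lay 0.98 (interval 0.49 to 1.69, widened for 4 lists and 2 arrays) above the endothelium median on replicate 1. On replicate 2 they lay 0.75 above it (interval 0.19 to 1.22). These intervals resample genes and not mice, and a lower share together with a change of the mesothelium stays open. The other lists lay above the endothelium median beyond their intervals on 1 array only. Gaps on replicates 1 and 2 were 0.18 and 0.55 for progenitors and fibroblasts and -0.53 and 0.50 for macrophages. For smooth muscle they were 1.13 and 0.032. Scaling is argued against, as the list lay -0.35 (interval -0.59 to -0.24) from the genes above background after quantile normalization. A change of the mesothelium itself, a diet effect and a trait of the single standard-diet mouse all stay open, because 1 array carries the standard label.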

How the results depend on the processing

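The restriction to genes above background, with either correlation, was chosen after seeing the data, and the other settings were planned. Of 681 gene comparisons over 106 gene results, array omissions aside, 644 had the direction and side of the threshold of the value reported, 27 passed only under the alternative and 10 reversed. The count of 0 genes past the threshold held in both directions with the mean of probe sets, without probe sets that can share transcripts, with the dim-gene filter, with quantile normalization, for every probe set by itself and at a threshold of 0.10. It moved to 66 higher and 37 lower genes with arrays centred on their medians and to 6 lower genes with a trend and robust estimation. The median difference of all genes was 0.08 as deposited, -0.0046 after quantile normalization and -0.24 after median centring. Of the genes 1.5-fold apart on both arrays, 74.2% were higher as deposited, 55.9% after quantile normalization and 56.6% after median centring. Starting from 2316 higher and 805 lower, that count was 469 and 209 over genes above the median signal, 238 and 116 above background, and 1479 and 413 at 2-fold. The lower count was 1250 after quantile normalization, 1394 after median centring and 1261 at 1.3-fold. With 1 high-calcium array left out it ranged from 2933 to 5898 higher and from 1959 to 2874 lower, since a single array then sets it. The 3 lists lower became 5 over genes above the median signal and 5 above background, each with 1 list higher, the mesothelium. The lists lower became 4 with camera on ranks, 1 after quantile normalization and 0 after median centring, with the estimated correlation over all genes or those above background, and with fry. The macrophage median was 0.092 without replicate 1 and -0.90 without replicate 2. Leaving out 1 array moved 27 genes by over 1.5 times, of which 10 reversed: without replicate 1 and without replicate 2 in turn, Adipoq was at -0.096 and 0.028, Agt at -0.78 and 0.072, Vdr at -0.21 and 0.76, Cd68 at 0.23 and -1.04, Myh11 at -0.90 and 4.195, Tpm2 at -0.93 and 3.62, Prm1 at -2.30 and 0.098, Prm2 at -2.90 and 0.42, Fcmr at -0.47 and 2.68, and Cd79b at -0.45 and 2.26. For genes, Fasn (-0.048), Scd1 (-0.16), Insr (-0.15) and Vdr (-0.046) turned after median centring, Vdr also after quantile normalization (-0.12) and with the mean of probe sets (-0.33). That mean turned Esrrg (0.31), Per3 (0.35) and Rapgef1 (-0.092), and leaving out shared probe sets turned Dbp (0.029). The cause was not tested. No test was possible with 1 high-calcium array left out, as no residual degrees of freedom remain. No paired analysis was possible because the labels pair no mice across the diets. Signal near background limits the ranking of dim genes.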

Other observations

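The simulation in the last paragraph and the restriction to genes above background were chosen after the data had been seen. Genes of oxidative phosphorylation were lower on both high-calcium arrays for 24 of 43 measured members and higher on both for 4, with a median log2 difference of -0.07 (camera adjusted p = 0.110). The list passed with camera on ranks (adjusted p = 0.0341) but not with the estimated correlation or with fry. Over all alternatives the adjusted p ranged from 0.0341 to 0.996. Ribosomal protein genes were higher on both arrays for 19 of 31 members, with a median of 0.08, whereas camera's direction was down (adjusted p = 0.980). Interferon response genes had a median of -0.12, with 17 of 32 lower on both (adjusted p = 0.110). The vitamin D and calcium handling list, of interest because the diets differ in calcium, had 10 members lower and 15 higher on both arrays of 38 measured, with an adjusted p of 0.859.

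The array of open diet gave the following values, from which no diet is inferred. Its log2 signal was 3.56 for Lep, 4.88 for Adipoq, 3.13 for Cd68, -0.47 for Lcn2, 1.11 for Aplnr, -2.72 for Myh11 and -3.69 for Prm1. Over 10463 genes above background on all 4 arrays, the SD of its log2 difference was 0.30 from high-calcium replicate 2, 0.34 from the standard array and 0.54 from high-calcium replicate 1. The 2 high-calcium arrays differed from each other by an SD of 0.52, and replicate 2 from the standard array by 0.36.

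Across the 10620 genes above background, the differences of the 2 high-calcium arrays from the standard array correlated with r = 0.29 and had a covariance of 0.05. Genes are not independent replicates. Simulated unchanged arrays that share a control gave a correlation of 0.50 and a covariance of 0.14. They carried the spread between the high-calcium arrays, which was wider than that between replicate 2 and the standard array. The comparison therefore cannot decide whether the diets differ.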
